A study of Homo sapiens with 32 samples.

How the data were processed

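According to the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and cutadapt 2.5, aligned to GRCh38 with STAR 2.5.3a and handled with SAMtools 1.10 and R 4.1.2. The deposited count table holds raw read counts per gene over exons with no normalization, as whole numbers for annotated genes and for 92 spike-in sequences in each of the 32 samples. The FPKM table was made by the authors, and count over FPKM equalled the product of 1 factor per gene and 1 factor per library. The FPKM values were used only for that test. Gene identifiers and coordinates are those of the deposited table. The program that counted reads, its strand setting and any filter are not stated, so counts of antisense, overlapping and paralogous genes are uncertain. Libraries were made by a standard RNA sequencing service from RNA of column-purified cells.

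Spike-in sequences were left out, and genes with enough counts by edgeR's filterByExpr were kept, which left 18206 genes in JJN3, 19064 in KMS11 and 20262 over all libraries. Library sizes were scaled by TMM. Each line was fitted apart with its 8 groups and 16 libraries, which leaves 8 residual degrees of freedom, and differences between lines were fitted on all 32 libraries with 16 residual degrees of freedom. All adjusted p-values of genes come from edgeR's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. There were 30 comparisons, 13 per line and 4 between lines. The replicate numbers were not used as pairs, because the labels name no batch or day for them, although KMS11 libraries with the same number deviated together. Standard errors are the absolute log2 change over the square root of F. With 2 libraries per group, no test on other splits of the samples and no outlier test of single groups could be made. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

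The comparisons, the test, 19 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover plasma cell and myeloma transcription factors, drug target and CRL4-CRBN components, the AP-1 and small MAF family, the MAF translocation signature, interferon-stimulated genes, MYC targets in ribosome biogenesis and nucleotide synthesis, S phase genes, G2/M genes, the unfolded protein response and ER chaperones, amino-acid response genes, the BCL2 family, NF-kappaB targets, antigen presentation, plasma cell surface receptors, cholesterol biosynthesis, glycolysis, B cell markers, markers of other blood and stromal cells, and the KMS11 t(4;14) genes. For each list the genes up and down are given over all genes tested and adjusted over the list alone. The 18 lists with at least 5 members were tested by camera on voom values with a preset inter-gene correlation of 0.01, and adjusted over the lists of a comparison. Of the 540 list tests 211 were called in this way, and 4 were called with an estimated correlation. Those 4 were the plasma cell surface receptors with GNE-781 in JJN3 cells with eGFP and with BATF, and the plasma cell surface receptors and the MAF translocation signature in the difference between lines in the effect of BATF. All other list calls rest on the preset correlation.

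Genes were named if they were on a panel (BATF, IRF4, MYC, IKZF1, IKZF3, CRBN, EP300, CREBBP, PRDM1, XBP1, MAF, CCND2 and BATF3), if they were among the 5 protein-coding genes with the largest fold in either direction with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the libraries of the groups (immunoglobulin genes left out), or if they were among up to 4 called members of a list. For differences of responses the rule on overlap did not apply. Genes outside this rule are named only where 5 or fewer were called or to describe RNA of other cells, and were then chosen after their values were seen. A library was said to carry blood genes at an HBB level of at least 50 CPM, and kidney-line genes at an IRS4 level of at least 10 CPM, limits set after the data were seen. A gene followed either set when it was at least 2-fold higher in the carrying library of every group in which 1 of the 2 libraries carried the set, on log2 CPM with a prior count of 1.

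Counts were simulated from gene means and dispersions of each line. For both drugs the test recovered 18.4% of 2-fold and 63.6% of 4-fold changes in JJN3 (92 genes called, 4 falsely). In KMS11 it recovered 4.08% and 53.1% (57 called, 2 falsely). For the difference BATF made to that response the shares were 9.18% and 46.5% in JJN3 and 2.04% and 27.1% in KMS11. A list of 31 members shifted in the simulation ranked first among the lists, and no other list was called. Correlation between genes was not simulated, so this does not test false list calls from it.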

Results

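Gene expression was measured by RNA sequencing of polyadenylated RNA in JJN3 and KMS11, 2 established human multiple myeloma cell lines. Both lines carry a translocation that activates the transcription factor gene MAF, and KMS11 also carries one that activates the receptor gene FGFR3 and the histone methyltransferase gene WHSC1. Cells of each line had been transduced with eGFP, the control, or with BATF, a basic leucine zipper transcription factor that pairs with JUN proteins and binds DNA together with IRF4. Each of these 4 cell populations was kept for 48 h with DMSO (the vehicle), with 200 nM pomalidomide, with 40 nM GNE-781 or with both drugs. Pomalidomide is an immunomodulatory drug that binds CRBN, the substrate receptor of a ubiquitin ligase, and so leads to the destruction of the lymphoid transcription factors IKZF1 and IKZF3. GNE-781 binds the bromodomain of the acetyltransferases EP300 and CREBBP, which act at enhancers. The 16 groups held 2 libraries each, 32 in all. Gene counts per library, in units of 1e6, were 18.2 to 22.7 in JJN3 and 19.1 to 24.3 in KMS11, with a median of 20.7. Levels are in CPM, read counts scaled to a library total of 1e6, as the mean ± SD of the 2 libraries of a group. Changes are log2 fold changes ± the standard error derived from F. For gene lists the median log2 change of the members is given with the test of the list against other genes. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values do not cover repeated experiments. They pool the spread of all groups fitted, which in JJN3 was larger with BATF than with eGFP.

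Some libraries held transcripts foreign to myeloma cells. HBB, a haemoglobin chain of red cells, stood at 215 to 1952 CPM in 11 libraries and at 1.36 to 4.88 CPM in the other 21. IRS4, an adaptor protein abundant in an embryonic kidney cell line, stood at 19.1 to 48.0 CPM in 9 libraries and at 0 to 1.16 CPM in the other 23. The blood genes were present in GNE-781 and both-drug replicate 1 of both lines with eGFP. With BATF they were present in JJN3 vehicle, pomalidomide and GNE-781 replicate 1, and in GNE-781 and both-drug replicate 2 of both lines. The kidney-line genes were present in vehicle replicate 2 with eGFP and vehicle replicate 1 with BATF in both lines. In KMS11 they were also in both-drug replicate 2 with eGFP and in replicate 2 of every BATF group. In 9 groups only 1 of the 2 libraries carried the blood genes, so these transcripts raised the spread within groups. No gene of the 255 following HBB was called, and 1 of the 233 following IRS4 was called in each of 3 JJN3 comparisons. They vary within groups by definition and are hard to call, so this does not clear the calls of foreign RNA. The 20 markers of other blood and stromal cells gave 0 calls in every comparison, although their median log2 change reached 4.56 with both drugs in JJN3 cells with eGFP and 3.13 in KMS11. XBP1, a factor of the plasma cell secretory programme, was chosen for reporting. It had 0 counts in all 32 libraries and could not be assessed (ENSG00000100219.15, chromosome 22, 28794555 to 28800597).

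**Figure D1:**
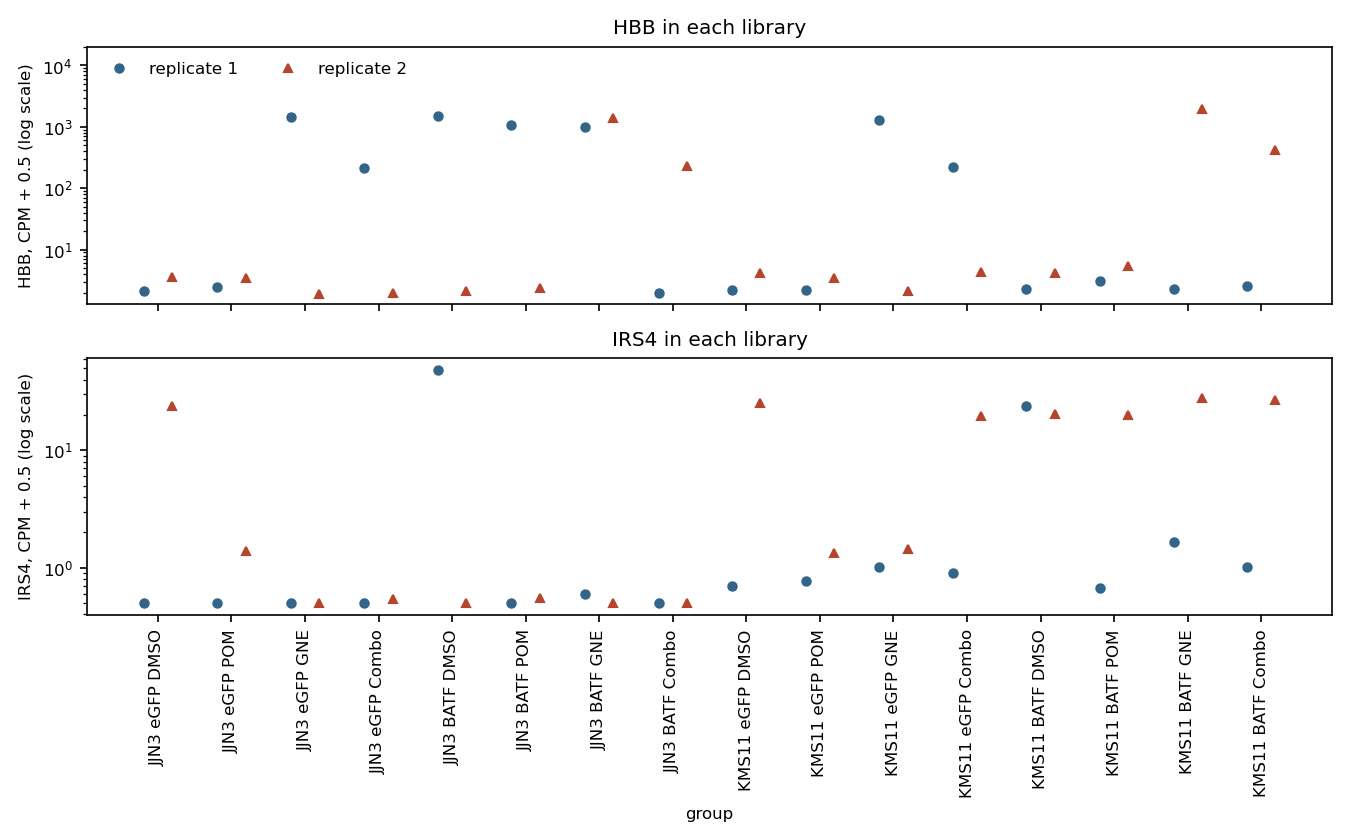
CPM of the red-cell gene HBB and the kidney-line gene IRS4, on log axes, in each of the 32 libraries by group and replicate. HBB lies at 215 or more in 11 libraries (others at most 4.88) and IRS4 at 19.1 or more in 9 (others at most 1.16).

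BATF was the transduced gene (ENSG00000156127.6, chromosome 14, 75522425 to 75547015), and its RNA was measured first to see how far the transduced cells differed from the controls. In JJN3 with vehicle it rose from 29.4 ± 3.15 CPM with eGFP to 285 ± 77.4 CPM with BATF (log2 fold change 3.28 ± 0.24, adjusted p = 0.00027). In KMS11 it rose from 17.3 ± 2.17 to 225 ± 66 CPM (log2 fold change 3.70 ± 0.33, adjusted p = 0.0052). Neither line with BATF showed a called change of BATF RNA with both drugs, with log2 fold changes of -0.01 ± 0.22 in JJN3 and -0.00 ± 0.29 in KMS11. In JJN3 cells with eGFP the endogenous transcript fell with both drugs (log2 fold change -0.82 ± 0.23, adjusted p = 0.03).

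**Figure D2:**
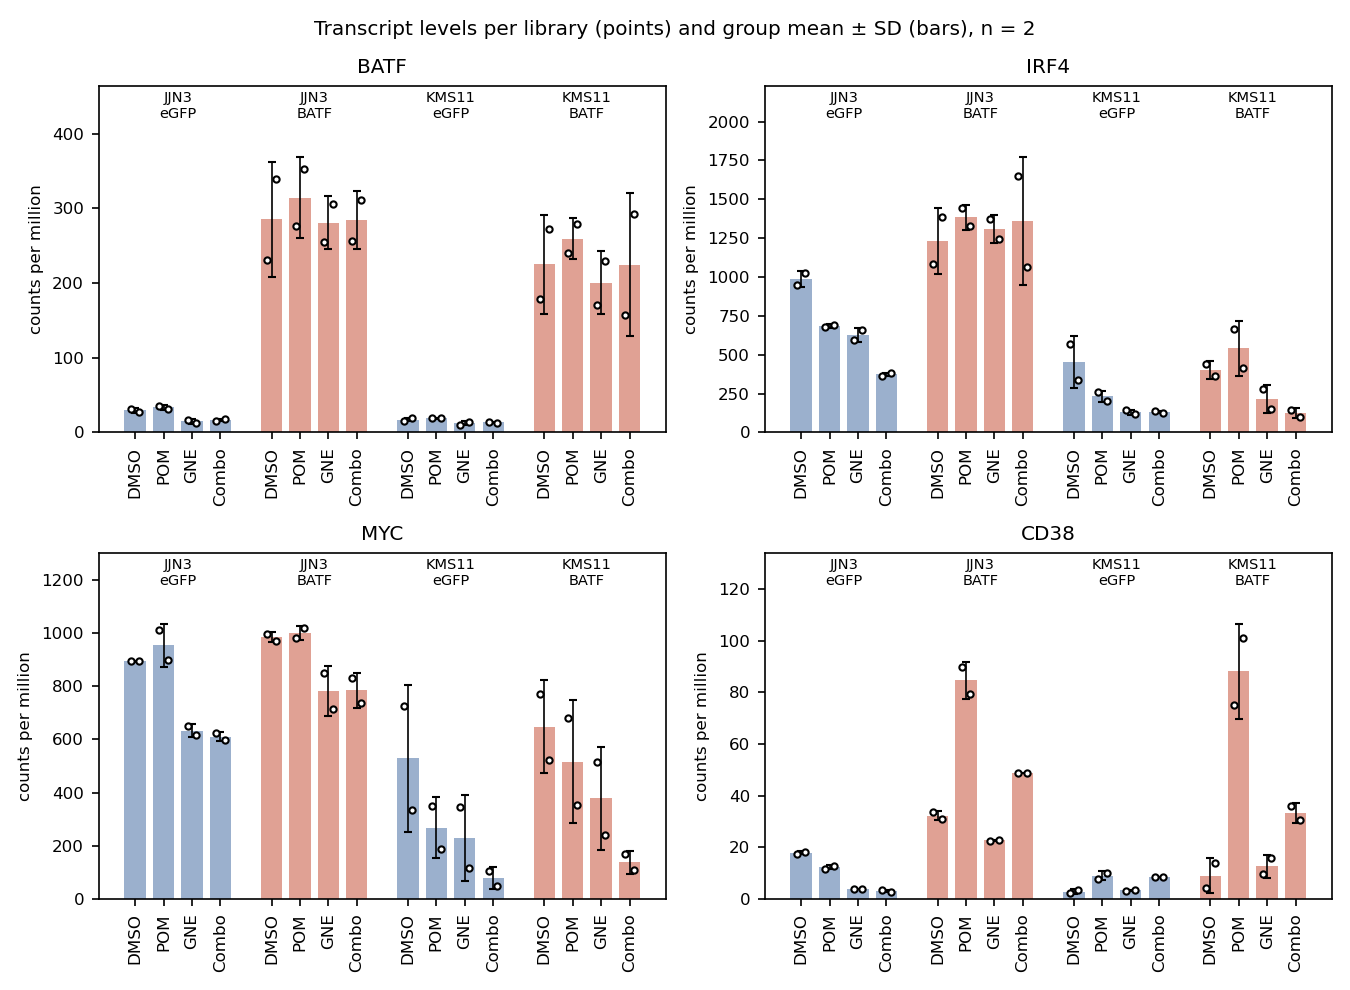
CPM of BATF, IRF4, MYC and CD38 in each of the 16 groups, with a point for each of the 2 libraries and a bar for the group mean ± SD. In JJN3, IRF4 is lowest with both drugs in cells with eGFP (373) and stays near its vehicle level in cells with BATF (1358 against 1234).

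**Figure D3:**
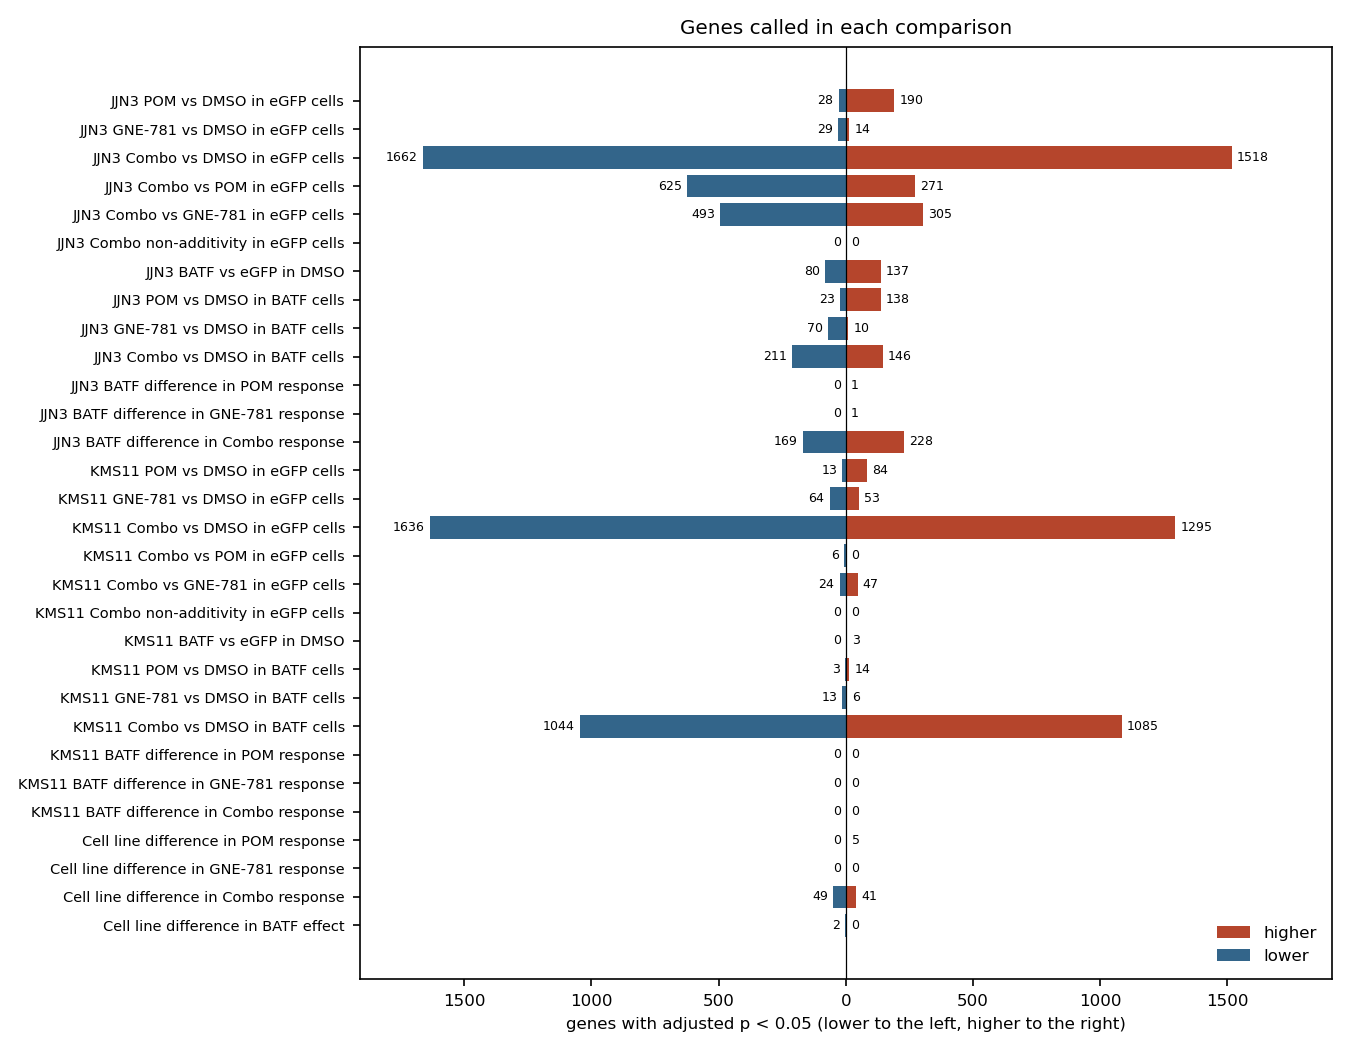
Number of genes called at an adjusted p under 0.05 in each comparison, up to the right and down to the left. Both drugs together gave the largest counts in JJN3 cells with eGFP (1518 up, 1662 down) and in KMS11 cells with eGFP (1295 up, 1636 down).

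Pomalidomide alone was compared with vehicle in JJN3 cells with eGFP to see which transcripts follow from engaging CRBN. The drug acted more by raising than by lowering transcripts, with 190 genes up and 28 down, of which 124 and 9 changed at least 2-fold. Regulators of cell death were among them. BMF, a pro-apoptotic protein of the BCL2 family that is held at the cytoskeleton, rose from 63.4 ± 1.8 to 280 ± 4.76 CPM (log2 fold change 2.14 ± 0.40, adjusted p = 0.035). BCL2L11, which encodes the death activator BIM, rose as well (log2 fold change 1.00 ± 0.20, adjusted p = 0.044). PTGIR, the prostacyclin receptor, had the largest fold of the named genes (6.55 ± 1.11), followed by IL3RA, the alpha chain of the interleukin 3 receptor (3.83 ± 0.40), and IGFBP3, a secreted binder of insulin-like growth factors (3.83 ± 0.41, from 11.7 ± 1.41 to 167 ± 1.4 CPM). ZP1, an egg-coat glycoprotein (3.80 ± 0.61), and CREB3L1, a membrane-bound transcription factor of the endoplasmic reticulum (3.56 ± 0.31), rose by similar folds. The NF-kappaB targets had 3 up and 0 down of 21 (4 and 0 adjusted over the list alone), among them BIRC3, an inhibitor of apoptosis (1.09 ± 0.19), RELB, a subunit of the noncanonical pathway (1.00 ± 0.14), and the deubiquitinase gene CYLD (0.71 ± 0.14). The NF-kappaB median was 0.50 (adjusted p = 6.2e-06, and adjusted p = 0.053 with an estimated correlation).

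Among the lineage factors that pomalidomide acts on, no fold was called at the RNA level. IRF4, the factor myeloma cells depend on (ENSG00000137265.13, chromosome 6, 391739 to 411447), had 985 ± 53 CPM with vehicle and 684 ± 11.2 CPM with pomalidomide (log2 fold change -0.53 ± 0.18, adjusted p = 0.27). MYC, the growth-promoting transcription factor (ENSG00000136997.13, chromosome 8, 127735434 to 127741434), differed by 0.09 ± 0.11. IKZF1 and IKZF3, whose proteins are the drug's targets, differed by 0.62 ± 0.18 and 0.05 ± 0.17. SPIB, an ETS factor of B cells (1.49 ± 0.29), and STAT3, the mediator of interleukin 6 signals (0.60 ± 0.12), rose. Of the interferon-stimulated genes IFIT3, an antiviral protein, rose (2.43 ± 0.37) and the list had 1 up and 0 down of 44 (4 and 0 adjusted over the list alone). The interferon median was 0.36 (adjusted p = 0.0049, and adjusted p = 0.47 with an estimated correlation). S phase genes had 0 up and 1 down of 31 (0 and 2 adjusted over the list alone), the called member being the cyclin gene CCNE1 (-0.99 ± 0.15). A median of -0.46 across the S phase list gave adjusted p = 1.3e-10, and adjusted p = 0.47 with an estimated correlation. HERPUD1, a component of protein degradation at the endoplasmic reticulum (0.75 ± 0.12), and ATF5, a factor of the amino-acid response (0.64 ± 0.13), were the called members of their lists. The amino-acid response genes had 1 up and 0 down of 23 (1 and 8 adjusted over the list alone). The amino-acid median was -0.70 (adjusted p = 6.3e-09, and adjusted p = 0.47 with an estimated correlation). The neuronal genes DIRAS1, a small GTPase (-1.77 ± 0.20), and MAP1B, a microtubule binder (-1.23 ± 0.25), fell. The call count rested on each library, with 0 and 20 without vehicle replicate 1 and 2 and 35 and 40 without pomalidomide replicate 1 and 2. Over the other settings it ran from 23 with all 32 libraries in 1 fit to 2035 with only the groups of the contrast.

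GNE-781 alone was compared with vehicle in the same cells to see which transcripts depend on the bromodomains of EP300 and CREBBP. It called fewer genes, 14 up and 29 down. CD38, an ectoenzyme and antibody target in myeloma (ENSG00000004468.11, chromosome 4, 15778275 to 15853230), fell from 17.8 ± 0.552 to 3.78 ± 0.0687 CPM (log2 fold change -2.23 ± 0.13, adjusted p = 6.1e-05). GPRC5D, an orphan receptor of plasma cells, fell by a similar fold (log2 fold change -2.35 ± 0.36, adjusted p = 0.033). TNFRSF17, the maturation antigen BCMA (ENSG00000048462.9, chromosome 16, 11965107 to 11968068), fell less (log2 fold change -1.25 ± 0.12, adjusted p = 0.0033). IL6R, the receptor for interleukin 6, a growth factor of myeloma, fell too (log2 fold change -2.22 ± 0.31, adjusted p = 0.023). The plasma cell surface receptors had 0 up and 4 down of 19 (0 and 5 adjusted over the list alone) and moved down against other genes. The surface receptor median was -0.86 (adjusted p = 1.1e-07, and adjusted p = 0.029 with an estimated correlation). INSIG1, which restrains sterol synthesis and is induced by the same factors as the synthesis enzymes, fell (-1.30 ± 0.18) as the only call in cholesterol biosynthesis, which had 0 up and 1 down of 24 (1 and 1 adjusted over the list alone). The cholesterol median was -0.25 (adjusted p = 0.0079, and adjusted p = 0.71 with an estimated correlation). The transcripts that rose included PINK1, a kinase that marks damaged mitochondria (1.43 ± 0.20), SYNJ2BP, a mitochondrial outer membrane protein (1.30 ± 0.16), and SNX10, a sorting nexin (1.01 ± 0.14). IRF4 stood at 627 ± 44.1 CPM (log2 fold change -0.65 ± 0.18, adjusted p = 0.18), below the threshold for a call. MYC stood at 633 ± 25.3 CPM (log2 fold change -0.50 ± 0.11, adjusted p = 0.10). It was called with the replicate number as a block (adjusted p = 0.026). Genes of S phase gave 0 of 31 called (0 up and 2 down adjusted over the list alone). The MYC targets in ribosome biogenesis and nucleotide synthesis gave 0 of 34 called (0 up and 0 down adjusted over the list alone). The S phase median was -0.46 (adjusted p = 1.5e-09, and adjusted p = 0.51 with an estimated correlation). The MYC target median was -0.30 (adjusted p = 1.1e-09, and adjusted p = 0.48 with an estimated correlation). Counts after leaving out a library were 1 and 4 without vehicle replicate 1 and 2 and 4 and 1 without GNE-781 replicate 1 and 2, and other settings gave 6 without kidney-line libraries to 736 with no low-count filter.

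Both drugs together were compared with vehicle in JJN3 cells with eGFP to see what the combination does beyond either drug. The response was larger, with 1518 genes up and 1662 down, 612 and 757 of them at least 2-fold. IRF4 fell from 985 ± 53 to 373 ± 12 CPM (log2 fold change -1.40 ± 0.18, adjusted p = 0.00083). MYC fell from 895 ± 1.86 to 610 ± 17.7 CPM (log2 fold change -0.55 ± 0.11, adjusted p = 0.0061). S phase genes had 0 up and 30 down of 31 (0 and 31 adjusted over the list alone), including E2F2, an activator of the G1/S programme (-2.98 ± 0.37), CDC45, part of the replicative helicase (-2.77 ± 0.28), MCM10, a replication initiation factor (-2.55 ± 0.41), and UHRF1, which guides maintenance DNA methylation (-2.51 ± 0.38). A median of -2.09 across the S phase list gave adjusted p = 3.9e-27, and adjusted p = 0.27 with an estimated correlation. G2/M genes had 0 up and 29 down of 30 (0 and 29 adjusted over the list alone), including the mitotic kinase genes AURKB (-1.73 ± 0.23) and AURKA (-1.49 ± 0.21) and the proliferation marker MKI67 (-1.61 ± 0.27). The G2/M median was -1.26 (adjusted p = 6e-20, and adjusted p = 0.27 with an estimated correlation). The MYC targets had 0 up and 24 down of 34 (0 and 33 adjusted over the list alone), with LYAR, a nucleolar regulator (-1.53 ± 0.18), and ODC1, the first enzyme of polyamine synthesis (-1.13 ± 0.25), among them. A median of -0.69 across the MYC target list gave adjusted p = 2.2e-16, and adjusted p = 0.27 with an estimated correlation. TNFRSF17 fell from 170 ± 14.3 to 23.7 ± 0.621 CPM (log2 fold change -2.84 ± 0.13, adjusted p = 4.4e-06). CD38 fell to 3.03 ± 0.497 CPM (log2 fold change -2.55 ± 0.13, adjusted p = 8.8e-06), and GPRC5D from 62.3 ± 7.07 to 6.91 ± 0.484 CPM (log2 fold change -3.17 ± 0.37, adjusted p = 0.00046). The surface receptors as a list had 0 up and 4 down of 19 (0 and 5 adjusted over the list alone). A median of -0.98 across the surface receptor list gave adjusted p = 0.00026, and adjusted p = 0.2 with an estimated correlation.

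FBP1, the gluconeogenic fructose bisphosphatase (-4.49 ± 1.02), AMPD1, an adenosine monophosphate deaminase (-4.21 ± 0.94), and INHBE, an inhibin subunit made under stress (-3.94 ± 0.85), fell the most of the named genes. PHGDH and PSAT1, enzymes of serine synthesis, fell (-2.56 ± 0.34 and -2.54 ± 0.46), as did SLC7A5, a carrier of large neutral amino acids (-1.89 ± 0.20). The amino-acid response genes had 1 up and 14 down of 23 (1 and 15 adjusted over the list alone). A median of -1.10 across the amino-acid list gave adjusted p = 2.5e-07, and adjusted p = 0.54 with an estimated correlation. Cholesterol biosynthesis had 1 up and 5 down of 24 (1 and 5 adjusted over the list alone), with INSIG1 at -1.93 ± 0.18, and glycolysis 1 up and 1 down of 21 (1 and 1 adjusted over the list alone). A median of -0.57 across the cholesterol list gave adjusted p = 0.00041, and adjusted p = 0.57 with an estimated correlation. The glycolysis median was -0.58 (adjusted p = 0.041, and adjusted p = 0.64 with an estimated correlation). BMF rose to 438 ± 11.9 CPM (log2 fold change 2.79 ± 0.41, adjusted p = 0.0015), and BCL2L11 (1.39 ± 0.20), BBC3, which encodes PUMA (1.25 ± 0.37), and BIK, a further BH3-only protein (1.18 ± 0.23), rose too. The BCL2 family had 6 up and 0 down of 16 (7 and 1 adjusted over the list alone), and as a list it did not move against other genes (adjusted p = 0.091). NF-kappaB targets went both ways, with 5 up and 3 down of 21 (7 and 3 adjusted over the list alone), TRAF1, an adaptor of TNF receptors, rising (1.22 ± 0.32) and the chemokine gene CCL3 falling (-2.80 ± 0.52). Interferon-stimulated genes had 7 up and 2 down of 44 (8 and 2 adjusted over the list alone). IFI6, an antiviral membrane protein (1.76 ± 0.40), and DDX60, a helicase (1.85 ± 0.57), rose while SAMD9L, an antiviral growth suppressor (-2.46 ± 0.30), fell. A median of 0.82 across the interferon list gave adjusted p = 0.00074, and adjusted p = 0.54 with an estimated correlation. LGALS3BP, a secreted interferon-induced glycoprotein (ENSG00000108679.11, chromosome 17, 78971238 to 78980109), rose from 2.92 ± 1.61 to 26.3 ± 1.71 CPM (log2 fold change 3.16 ± 0.61, adjusted p = 0.006), and CREB3L1 (4.78 ± 0.32) and ZP1 (5.08 ± 0.64) rose further than with pomalidomide.

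The plasma cell and myeloma transcription factors had 1 up and 7 down of 21 (2 and 7 adjusted over the list alone), with POU2F2 (-1.74 ± 0.48), an octamer-binding factor of B cells, and its coactivator POU2AF1 falling. WHSC1 fell (-1.31 ± 0.17), and the KMS11 t(4;14) genes, FGFR3 and WHSC1, had 0 up and 1 down of 2 (0 and 2 adjusted over the list alone) here. The drug-target list had 4 up and 0 down of 12 (4 and 0 adjusted over the list alone), CRBN (log2 fold change 0.35 ± 0.08, adjusted p = 0.017) and CREBBP (log2 fold change 0.48 ± 0.14, adjusted p = 0.032) rising by less than a doubling of their RNA. EP300 was not called with both drugs (log2 fold change 0.36 ± 0.15, adjusted p = 0.12), nor was BATF3, the closest relative of BATF in the AP-1 list (log2 fold change -0.62 ± 1.04, adjusted p = 0.74). The AP-1 and small MAF family had 1 up and 2 down of 13 (1 and 2 adjusted over the list alone), and the unfolded protein response and ER chaperones 3 up and 2 down of 28 (3 and 2 adjusted over the list alone). Antigen presentation had 0 up and 2 down of 22 (0 and 2 adjusted over the list alone), the B cell markers 0 of 13 called (0 up and 0 down adjusted over the list alone), and the MAF translocation signature 0 of 9 called (0 up and 0 down adjusted over the list alone). MAF itself differed by 0.65 ± 0.24 and CCND2, the cyclin D gene it drives, by -0.84 ± 0.30, neither called here but both with the replicate block (adjusted p = 0.025 and 0.0041). Fewer genes were called with each library left out, 1315 and 1453 without vehicle replicate 1 and 2 and 1291 and 1172 without both-drug replicate 1 and 2, and other settings gave 1627 with all 32 libraries in 1 fit to 6072 with only the groups of the contrast.

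**Figure D4:**
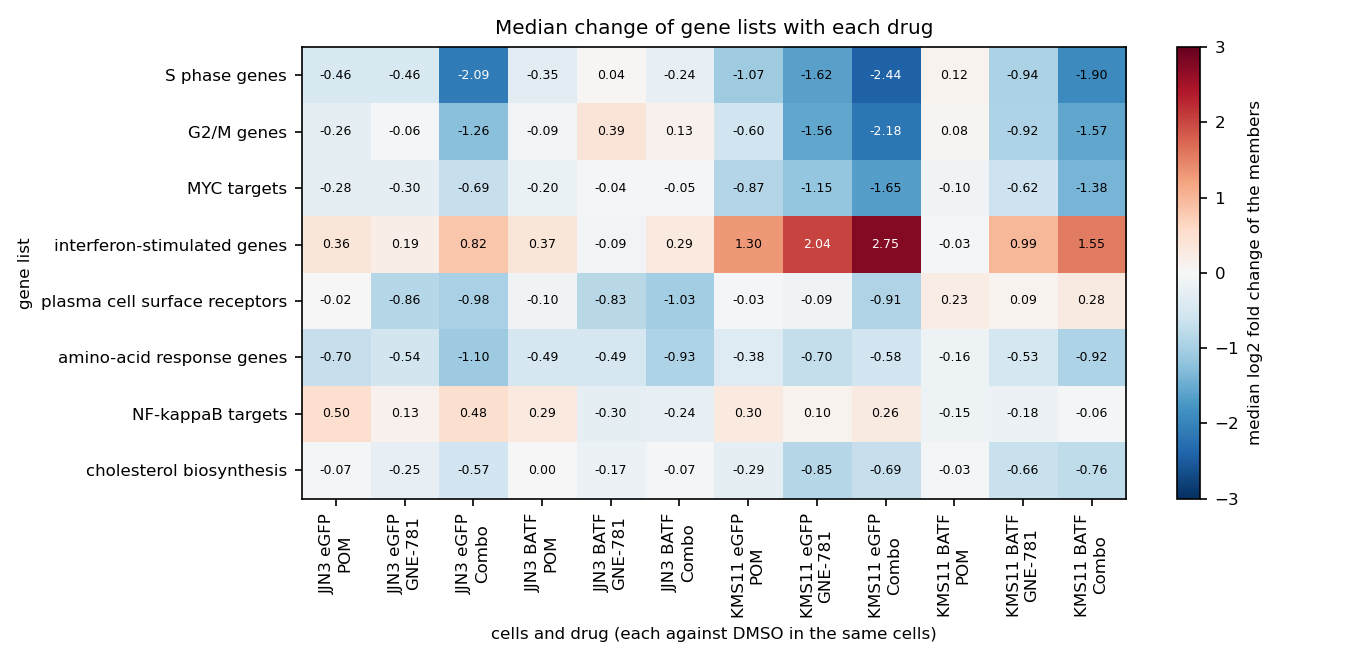
Median log2 fold change of the genes of each list, colour scale, for the drug comparisons with vehicle in the 4 cell populations. With both drugs the S phase median is -2.09 in JJN3 with eGFP and -0.24 in JJN3 with BATF, and -2.44 and -1.90 in KMS11.

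The combination was then set against each drug alone in JJN3 cells with eGFP, to see what the added drug contributed. Adding GNE-781 to pomalidomide gave 271 genes up and 625 down, and adding pomalidomide to GNE-781 gave 305 up and 493 down. IRF4 fell in both, against pomalidomide (log2 fold change -0.88 ± 0.18, adjusted p = 0.022) and against GNE-781 (log2 fold change -0.75 ± 0.18, adjusted p = 0.045). MYC fell against pomalidomide (log2 fold change -0.64 ± 0.11, adjusted p = 0.009) but not against GNE-781 (log2 fold change -0.05 ± 0.11, adjusted p = 0.91). Its level was 610 ± 17.7 CPM with both drugs and 633 ± 25.3 CPM with GNE-781 alone. Against pomalidomide, S phase genes had 0 up and 25 down of 31 (0 and 31 adjusted over the list alone) with a median of -1.57 (adjusted p = 1.5e-31, and adjusted p = 0.21 with an estimated correlation), and G2/M genes 0 up and 15 down of 30 (0 and 30 adjusted over the list alone). Against GNE-781 the S phase genes had 0 up and 22 down of 31 (0 and 31 adjusted over the list alone) with a median of -1.69 (adjusted p = 1.5e-36, and adjusted p = 0.17 with an estimated correlation), and G2/M genes 0 up and 25 down of 30 (0 and 29 adjusted over the list alone). Adding GNE-781 to pomalidomide left antigen presentation with 0 up and 1 down of 22 (0 and 10 adjusted over the list alone), with CIITA, the master regulator of class II genes, falling (-1.41 ± 0.34), and TNFRSF17 fell (-2.38 ± 0.12). The largest falls of the named genes were in CHRNA6, a nicotinic receptor subunit (-4.45 ± 0.58), and DNAJC5B, a cysteine-string protein (-3.36 ± 0.43). Against GNE-781, BMF (1.89 ± 0.40), CREB3L1 (4.29 ± 0.32) and COL16A1, a fibril-associated collagen (4.96 ± 0.48), rose, as pomalidomide alone had raised the first pair, and RRM2, the small subunit of ribonucleotide reductase, fell (-2.21 ± 0.21). MYH7B, a myosin heavy chain, rose in both (2.45 ± 0.27 and 4.80 ± 0.30). The counts against pomalidomide were 170 and 152 without pomalidomide replicate 1 and 2 and 87 and 84 without both-drug replicate 1 and 2, and in other settings 148 with all 32 libraries in 1 fit to 4422 with only the groups of the contrast. Those against GNE-781 were 201 and 97 without GNE-781 replicate 1 and 2 and 111 and 114 without both-drug replicate 1 and 2, and in other settings 110 with all 32 libraries in 1 fit to 2916 with only the groups of the contrast.

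Whether the drugs together did more than the sum of their separate effects was tested gene by gene in JJN3 cells with eGFP. The fit used here called 0 genes, with 622 at an unadjusted p under 0.05 where chance would give 910.3. DESeq2 called 55, and edgeR called 18 with the replicate block, 165 with no low-count filter and 394 when fitted on only the groups of the contrast. Departures from additivity are therefore neither shown nor excluded. As lists, S phase genes had 0 of 31 called (0 up and 16 down adjusted over the list alone) and G2/M genes 0 of 30 called (0 up and 22 down adjusted over the list alone), and both medians lay below additivity on the log2 scale. A median of -1.13 across the S phase list gave adjusted p = 1.1e-38, and adjusted p = 0.12 with an estimated correlation. A median of -0.96 across the G2/M list gave adjusted p = 3.6e-39, and adjusted p = 0.12 with an estimated correlation. IRF4 departed from additivity by -0.22 ± 0.26.

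BATF was compared with eGFP in JJN3 under vehicle to see what the transduced factor changes by itself. It raised 137 genes and lowered 80. TOX, a chromatin factor of activated T cells (5.41 ± 0.74), GPR15, a homing receptor (6.31 ± 1.12), and IGFBP4, a binder of insulin-like growth factors (4.18 ± 0.75), rose. IKZF1 rose from 111 ± 14.1 to 216 ± 18.2 CPM (log2 fold change 0.96 ± 0.18, adjusted p = 0.032), and CD38 from 17.8 ± 0.552 to 32.2 ± 1.82 CPM (log2 fold change 0.85 ± 0.12, adjusted p = 0.0064). STAT4, a signal transducer downstream of interleukin 12 (-2.35 ± 0.20), IL4I1, a secreted amino-acid oxidase (-2.20 ± 0.32), and SPIB (-1.66 ± 0.30) fell. So did the NF-kappaB targets TNFAIP3, an inhibitor of the pathway (-0.83 ± 0.11), and NFKB2 (-0.79 ± 0.16). IRF4 had 985 ± 53 and 1234 ± 213 CPM (log2 fold change 0.32 ± 0.18, adjusted p = 0.43), and PRDM1, the plasma cell repressor, differed by 1.45 ± 0.42 (adjusted p = 0.17). The AP-1 and small MAF family had 1 up and 0 down of 13 (4 and 0 adjusted over the list alone), and the transcription factors 1 up and 1 down of 21 (6 and 2 adjusted over the list alone). B cell markers had 0 of 13 called (0 up and 0 down adjusted over the list alone) and a median log2 change of 3.53, in a comparison where 1 of the 4 libraries carried blood genes. The count changed with the libraries used, 36 and 49 without eGFP vehicle replicate 1 and 2 and 118 and 161 without BATF vehicle replicate 1 and 2, and other settings gave 0 with only the groups of the contrast to 1884 with no low-count filter.

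The drugs were then given to JJN3 cells with BATF, to see whether the factor alters the responses. Pomalidomide raised 138 genes and lowered 23. CXCL11, an interferon-induced chemokine (4.92 ± 0.55), CFB, complement factor B (3.95 ± 0.64), CCDC80, a matrix protein (4.58 ± 0.31), IFIT3 (2.42 ± 0.37) and CIITA (2.15 ± 0.35) rose. CD38 rose from 32.2 ± 1.82 to 84.6 ± 7.2 CPM (log2 fold change 1.39 ± 0.12, adjusted p = 0.0012). NF-kappaB targets had 2 up and 0 down of 21 (6 and 0 adjusted over the list alone), and antigen presentation 1 up and 0 down of 22 (8 and 0 adjusted over the list alone). A median of 0.29 across the NF-kappaB list gave adjusted p = 0.00027, and adjusted p = 0.18 with an estimated correlation. A median of 0.48 across the antigen presentation list gave adjusted p = 3.4e-07, and adjusted p = 0.54 with an estimated correlation. GNE-781 raised 10 genes and lowered 70, with KCNH5, a potassium channel (-2.88 ± 0.47), GPRC5D (-2.05 ± 0.35), TNFRSF17 (-1.61 ± 0.12), POU2AF1 (-1.15 ± 0.19) and INSIG1 (-1.45 ± 0.18) falling. The surface receptors had 0 up and 2 down of 19 (0 and 7 adjusted over the list alone). For the surface receptor list the median was -0.83 (adjusted p = 3.2e-07, and adjusted p = 0.038 with an estimated correlation). For pomalidomide the count was 63 and 105 without vehicle replicate 1 and 2 and 75 and 60 without pomalidomide replicate 1 and 2, and in other settings 0 with only the groups of the contrast to 696 with no low-count filter. For GNE-781 it was 15 and 54 without vehicle replicate 1 and 2 and 1 and 2 without GNE-781 replicate 1 and 2, and in other settings 0 with only the groups of the contrast to 576 with no low-count filter.

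With both drugs JJN3 cells with BATF changed 357 genes, 146 up and 211 down. IRF4 stayed near its vehicle level, 1358 ± 411 against 1234 ± 213 CPM (0.14 ± 0.18, adjusted p = 0.8). MYC had 785 ± 66 against 984 ± 18.4 CPM (-0.33 ± 0.11, adjusted p = 0.17). The genes of S phase had 0 up and 1 down of 31 (0 and 1 adjusted over the list alone), unlike the 30 that fell with eGFP. For the S phase list the median was -0.24 (adjusted p = 0.0097, and adjusted p = 0.79 with an estimated correlation). G2/M genes had 0 of 30 called (0 up and 0 down adjusted over the list alone) with a median of 0.13 (-0.38 without libraries carrying blood genes), and MYC targets 0 of 34 called (0 up and 0 down adjusted over the list alone) with a median of -0.05. The surface receptors had 1 up and 5 down of 19 (1 and 6 adjusted over the list alone). TNFRSF17 fell from 183 ± 28.5 to 44.8 ± 0.304 CPM (log2 fold change -2.03 ± 0.12, adjusted p = 9.8e-05), and GPRC5D (-2.07 ± 0.35), the costimulatory receptor CD28 (-2.35 ± 0.44) and the adhesion ligand CD48 (-1.80 ± 0.39) fell too. The surface receptor median was -1.03 (adjusted p = 0.00054, and adjusted p = 0.22 with an estimated correlation). The amino-acid response genes had 0 up and 5 down of 23 (1 and 13 adjusted over the list alone), SLC7A5 (-1.09 ± 0.19) and the stress pseudokinase gene TRIB3 (-1.03 ± 0.16) falling. For the amino-acid list the median was -0.93 (adjusted p = 2.9e-09, and adjusted p = 0.5 with an estimated correlation). ASS1, an enzyme of arginine synthesis, fell (-3.44 ± 0.60), and LGALS3BP rose (4.39 ± 0.65). Single libraries moved the count to 161 and 363 without vehicle replicate 1 and 2 and 87 and 173 without both-drug replicate 1 and 2, and other settings gave 0 with only the groups of the contrast to 1200 with no low-count filter.

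The difference of these responses was tested directly in JJN3, as the drug effect with BATF minus that with eGFP. For both drugs 397 genes differed, 228 with a response more positive with BATF and 169 more negative. IRF4 was one of them (log2 difference 1.54 ± 0.26, adjusted p = 0.017). MYC was not (0.23 ± 0.15, adjusted p = 0.53). CD38 had the largest positive difference of the named genes (3.15 ± 0.17, adjusted p = 4e-05). It fell with eGFP and stood at 48.8 ± 0.0973 CPM with BATF. S phase genes had 15 up and 0 down of 31 (30 and 0 adjusted over the list alone). They included UHRF1 (2.38 ± 0.52), CDC45 (2.32 ± 0.38), EXO1, an exonuclease (2.17 ± 0.43), and RRM2 (2.22 ± 0.29). RAD54L, a recombination motor, was called too (2.24 ± 0.31). The S phase median was 1.73 (adjusted p = 1.4e-31, and adjusted p = 0.18 with an estimated correlation). G2/M genes had 11 up and 0 down of 30 (29 and 0 adjusted over the list alone), with AURKB (1.57 ± 0.31) and CDK1, the mitotic cyclin-dependent kinase (1.56 ± 0.31). MYC targets had 3 up and 0 down of 34 (19 and 0 adjusted over the list alone). For the G2/M list the median was 1.38 (adjusted p = 4.9e-28, and adjusted p = 0.18 with an estimated correlation). For the MYC target list the median was 0.66 (adjusted p = 4.1e-18, and adjusted p = 0.21 with an estimated correlation). On the negative side stood IGFBP3 (-4.96 ± 0.56), ZP1 (-4.34 ± 0.85), ACHE, the acetylcholinesterase gene (-4.31 ± 0.63), and CREB3L1 (-4.11 ± 0.43). Both drugs had raised ZP1 and CREB3L1 with eGFP. The BCL2 family had 0 up and 2 down of 16 (0 and 5 adjusted over the list alone), namely BIK (-1.70 ± 0.33) and BCL2L11 (-1.28 ± 0.28). The BCL2 family median was -0.63 (adjusted p = 0.0055, and adjusted p = 0.18 with an estimated correlation). The count was 34 and 36 without eGFP vehicle replicate 1 and 2, 30 and 11 without eGFP both-drug replicate 1 and 2, 110 and 978 without BATF vehicle replicate 1 and 2 and 104 and 83 without BATF both-drug replicate 1 and 2. Other settings gave 1 with only the groups of the contrast to 1355 with the replicate block, and 31 without the libraries carrying blood genes, where 0 S phase and 0 G2/M genes were called.

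For pomalidomide alone and for GNE-781 alone, 1 gene differed between the responses of JJN3 cells with BATF and with eGFP, and it was CD38 both times (1.93 ± 0.17, adjusted p = 0.0039, and 1.73 ± 0.17, adjusted p = 0.015). CD38 is on a fixed list but was singled out here after its values were seen. At an unadjusted p under 0.05 there were 291 and 543 genes, DESeq2 called 7 and 18, and edgeR with no low-count filter 47 and 257. Neither call was made with all 32 libraries in 1 fit or with only the groups of the contrast. The pomalidomide call was lost without eGFP pomalidomide replicate 1 (0 genes). For GNE-781 the counts were 0 and 0 without eGFP vehicle replicate 1 and 2, 0 and 0 without eGFP GNE-781 replicate 1 and 2, 0 and 2 without BATF vehicle replicate 1 and 2 and 0 and 0 without BATF GNE-781 replicate 1 and 2.

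In KMS11 cells with eGFP, pomalidomide was compared with vehicle to ask the same question in the second line. It raised 84 genes and lowered 13. LGALS3BP rose from 5.84 ± 2.99 to 347 ± 40.1 CPM (log2 fold change 5.89 ± 0.94, adjusted p = 0.025). With it rose MME, the peptidase CD10 of early B cells (4.95 ± 0.57), BTBD17 (6.46 ± 0.96), MYH7B (4.70 ± 0.39) and HS3ST5, a heparan sulfate sulfotransferase (4.37 ± 0.60). ITGB7, an integrin subunit induced by MAF, rose from 1528 ± 69.6 to 4821 ± 1403 CPM (log2 fold change 1.66 ± 0.28, adjusted p = 0.031). The MAF translocation signature had 1 up and 0 down of 9 (1 and 1 adjusted over the list alone). ITGA8, an integrin alpha subunit (-3.69 ± 0.43), ANKLE1, a nuclease (-2.19 ± 0.40), CCNB3, a B-type cyclin (-1.82 ± 0.30), and SLBP, which binds histone messages (-1.10 ± 0.18), fell. Interferon-stimulated genes had 1 up and 0 down of 44 (1 and 0 adjusted over the list alone) but a high median, and S phase genes 0 up and 1 down of 31 (0 and 1 adjusted over the list alone). For the interferon list the median was 1.30 (adjusted p = 5.7e-09, and adjusted p = 0.76 with an estimated correlation). A median of -1.07 across the S phase list gave adjusted p = 2.5e-12, and adjusted p = 0.76 with an estimated correlation. IRF4 differed by -0.97 ± 0.35 and MYC by -0.98 ± 0.65, neither called here but both with the replicate block (adjusted p = 0.0070 and 0.012). Leaving out libraries gave 3 and 3 without vehicle replicate 1 and 2 and 50 and 5 without pomalidomide replicate 1 and 2, and other settings 0 without kidney-line libraries to 2981 with the replicate block.

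GNE-781 in KMS11 cells with eGFP raised 53 genes and lowered 64. TNFRSF17 fell from 126 ± 51.2 to 9.94 ± 1.81 CPM (log2 fold change -3.66 ± 0.68, adjusted p = 0.046), and the octamer coactivator gene POU2AF1 with it (log2 fold change -1.68 ± 0.20, adjusted p = 0.0094). The other falls included IGLL5, an immunoglobulin lambda-like gene whose reads can be shared with the lambda locus (-4.28 ± 0.48), the progenitor factor MYB (-3.04 ± 0.21) and ELL2, an elongation factor for secretory immunoglobulin messages (-1.24 ± 0.17). CAV1, the coat protein of caveolae, fell too (-2.89 ± 0.21), and IL11RA, a cytokine receptor (1.76 ± 0.31), and LOXL4, a lysyl oxidase (2.06 ± 0.33), rose. IRF4 stood at 129 ± 18.2 CPM against 453 ± 165 with vehicle, just short of a call here (log2 fold change -1.81 ± 0.35, adjusted p = 0.052) and called with the replicate block (adjusted p = 0.00029). S phase genes had 0 up and 2 down of 31 (0 and 29 adjusted over the list alone), with the cyclin gene CCNE2 called (-1.93 ± 0.30). G2/M genes had 0 up and 1 down of 30 (0 and 29 adjusted over the list alone), with the checkpoint kinase gene BUB1 (-1.96 ± 0.34). For the S phase list the median was -1.62 (adjusted p = 1.4e-18, and adjusted p = 0.28 with an estimated correlation). The G2/M median was -1.56 (adjusted p = 1.5e-17, and adjusted p = 0.28 with an estimated correlation). MYC targets had 0 of 34 called (0 up and 26 down adjusted over the list alone). A median of -1.15 across the MYC target list gave adjusted p = 8.6e-15, and adjusted p = 0.3 with an estimated correlation. Leaving out libraries gave 7 and 134 without vehicle replicate 1 and 2 and 3 and 3 without GNE-781 replicate 1 and 2, and other settings 0 without kidney-line libraries to 4660 with the replicate block.

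Both drugs in KMS11 cells with eGFP raised 1295 genes and lowered 1636, of which 842 and 1073 changed at least 2-fold. IRF4 fell from 453 ± 165 to 133 ± 7.36 CPM (log2 fold change -1.77 ± 0.35, adjusted p = 0.013). MYC fell from 529 ± 276 to 77.1 ± 41.3 CPM (log2 fold change -2.78 ± 0.68, adjusted p = 0.025), and MAF fell as well (log2 fold change -0.74 ± 0.22, adjusted p = 0.048). All the S phase genes fell, with 0 up and 31 down of 31 (0 and 31 adjusted over the list alone), among them the origin licensing factor CDC6 (-3.32 ± 0.69) and MCM10 (-3.30 ± 0.79). G2/M genes had 0 up and 27 down of 30 (0 and 29 adjusted over the list alone). The S phase median was -2.44 (adjusted p = 9.8e-19, and adjusted p = 0.41 with an estimated correlation). A median of -2.18 across the G2/M list gave adjusted p = 3.7e-16, and adjusted p = 0.41 with an estimated correlation. MYC targets had 0 up and 28 down of 34 (0 and 33 adjusted over the list alone). For the MYC target list the median was -1.65 (adjusted p = 2.6e-16, and adjusted p = 0.41 with an estimated correlation). LGALS3BP reached 701 ± 95.7 CPM (log2 fold change 6.91 ± 0.98, adjusted p = 0.0048). Interferon-stimulated genes had 17 up and 0 down of 44 (36 and 0 adjusted over the list alone), with the antiviral genes IFITM3 (5.80 ± 1.57), IFI27 (5.61 ± 1.52) and RSAD2 (5.09 ± 1.26). BATF2, an interferon-induced relative of BATF, rose as well (4.56 ± 0.79). A median of 2.75 across the interferon list gave adjusted p = 1.8e-14, and adjusted p = 0.44 with an estimated correlation. Antigen presentation had 4 up and 0 down of 22 (4 and 0 adjusted over the list alone), including the class I gene HLA-B (1.09 ± 0.24), whose reads can be shared with related genes.

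Among the plasma cell surface receptors, both drugs in KMS11 cells with eGFP gave 1 up and 6 down of 19 (1 and 9 adjusted over the list alone). A median of -0.91 across the surface receptor list gave adjusted p = 0.009, and adjusted p = 0.31 with an estimated correlation. TNFRSF17 fell from 126 ± 51.2 to 7.42 ± 1.27 CPM (log2 fold change -4.08 ± 0.69, adjusted p = 0.0083). TNFRSF13B, the related receptor TACI (-3.72 ± 0.55), and SLAMF7, an antibody target (-2.80 ± 0.59), fell too. FGFR3, driven by the translocation in this line, fell from 2699 ± 901 to 691 ± 164 CPM (log2 fold change -1.97 ± 0.41, adjusted p = 0.016), and POU2AF1 fell (-2.60 ± 0.20). BMF rose (2.07 ± 0.62), as did MCL1, the survival protein of plasma cells (0.61 ± 0.16), in a BCL2 family with 3 up and 0 down of 16 (3 and 0 adjusted over the list alone). MMP13, a collagenase (7.70 ± 1.44), and HSD11B1, which activates cortisol (6.67 ± 1.35), rose, and ACTL8, an actin-like protein of testis (-5.54 ± 1.33), and ITGA8 (-4.92 ± 0.46) fell. LDHA, lactate dehydrogenase, fell (-1.56 ± 0.33). Cholesterol biosynthesis had 0 up and 7 down of 24 (0 and 10 adjusted over the list alone), glycolysis 0 up and 4 down of 21 (1 and 5 adjusted over the list alone), and the amino-acid response genes 1 up and 3 down of 23 (1 and 5 adjusted over the list alone). Leaving out libraries gave 92 and 2466 without vehicle replicate 1 and 2 and 108 and 576 without both-drug replicate 1 and 2, and other settings 0 without kidney-line libraries to 7254 with the replicate block. Without libraries carrying blood genes 73 were called.

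The combination was set against the single drugs in KMS11 cells with eGFP as well. Against pomalidomide 6 genes fell and none rose. They were POU2AF1 (-2.27 ± 0.20), MYB (-1.90 ± 0.21), CCNE2 (-2.41 ± 0.31), CAV1 (-1.85 ± 0.20), SYNDIG1, a synaptic membrane protein (-1.56 ± 0.19), and the lambda joining segment IGLJ1 (-2.51 ± 0.32), the last chosen after its values were seen. At an unadjusted p under 0.05 there were 2030 genes, and S phase genes had 0 up and 1 down of 31 (0 and 24 adjusted over the list alone). A median of -1.51 across the S phase list gave adjusted p = 2.3e-16, and adjusted p = 0.36 with an estimated correlation. Against GNE-781, 47 genes rose and 24 fell. MME (4.41 ± 0.56), MUC1, a membrane mucin (4.49 ± 0.52), and BATF2 (4.41 ± 0.78) rose, and ETS1, a lymphoid ETS factor (-1.02 ± 0.17), LPXN, a focal adhesion adaptor (-1.99 ± 0.21), and ITGA8 (-3.96 ± 0.44) fell. No gene was called as departing from additivity in the fit used here, with 389 at an unadjusted p under 0.05, 3 called by DESeq2 and 90 by edgeR with no low-count filter. Against pomalidomide the count was 0 and 3 without pomalidomide replicate 1 and 2 and 0 and 0 without both-drug replicate 1 and 2. Against GNE-781 it was 0 and 1 without GNE-781 replicate 1 and 2 and 7 and 20 without both-drug replicate 1 and 2. These small counts rest on a fit without pairs: with the replicate number as a block, 1460 and 1213 genes were called in KMS11, near the 1833 and 1624 of JJN3.

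BATF changed 3 genes against eGFP in KMS11 under vehicle, all upward, while 1082 had an unadjusted p under 0.05, DESeq2 called 215 and edgeR with the replicate block 303. Apart from BATF they were MSX1, a homeobox repressor (log2 fold change 3.28 ± 0.31, adjusted p = 0.0052), and CFAP58, a protein of cilia (log2 fold change 4.02 ± 0.43, adjusted p = 0.012). IRF4 had 453 ± 165 and 402 ± 57.4 CPM. In this comparison 3 of the 4 libraries carried kidney-line genes, and the counts were 0 and 0 without eGFP vehicle replicate 1 and 2 and 1 and 2 without BATF vehicle replicate 1 and 2.

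In KMS11 cells with BATF, pomalidomide raised 14 genes and lowered 3, and GNE-781 raised 6 and lowered 13. With pomalidomide CD38 rose from 9.01 ± 6.66 to 88.1 ± 18.4 CPM (log2 fold change 3.29 ± 0.49, adjusted p = 0.046), with CFI, a complement protease (4.72 ± 0.49), MUC1 (4.18 ± 0.52) and CCR3, a chemokine receptor (3.27 ± 0.48), and ETS1 fell (-1.54 ± 0.17). With GNE-781 CASP1, the inflammatory caspase, rose (2.27 ± 0.31), and POU2AF1 (-1.59 ± 0.19), IGLL5 (-3.27 ± 0.45) and ADA, adenosine deaminase (-2.24 ± 0.32), fell. Both drugs gave 1085 genes up and 1044 down. IRF4 fell from 402 ± 57.4 to 124 ± 31.9 CPM (log2 fold change -1.70 ± 0.35, adjusted p = 0.018), and MYC had 648 ± 176 and 138 ± 43.1 CPM (log2 fold change -2.23 ± 0.67, adjusted p = 0.056, and adjusted p = 7.2e-05 with the replicate block). In S phase genes there were 0 up and 21 down of 31 (0 and 31 adjusted over the list alone), in G2/M genes 0 up and 9 down of 30 (0 and 28 adjusted over the list alone) and in MYC targets 0 up and 19 down of 34 (0 and 30 adjusted over the list alone). The S phase median was -1.90 (adjusted p = 6.4e-16, and adjusted p = 0.56 with an estimated correlation). For the G2/M list the median was -1.57 (adjusted p = 8.2e-13, and adjusted p = 0.56 with an estimated correlation). The MYC target median was -1.38 (adjusted p = 5.4e-15, and adjusted p = 0.56 with an estimated correlation). TNFRSF17 (-4.65 ± 0.72) and the chemokine receptor gene CCR8 (-4.94 ± 1.39) fell. IL10, an anti-inflammatory cytokine (6.22 ± 0.95), LGALS3BP (5.47 ± 0.92), BACH2, a repressor of the plasma cell fate, BCL2 (1.51 ± 0.27) and CD38 (log2 fold change 1.89 ± 0.47, adjusted p = 0.031) rose. For pomalidomide the count was 0 and 0 without vehicle replicate 1 and 2 and 0 and 4 without pomalidomide replicate 1 and 2. For GNE-781 it was 6 and 0 without vehicle replicate 1 and 2 and 0 and 0 without GNE-781 replicate 1 and 2. For both drugs it was 235 and 526 without vehicle replicate 1 and 2 and 196 and 693 without both-drug replicate 1 and 2. The replicate block called 467, 2027 and 6957 genes, and the groups of the contrast alone 0, 0 and 489.

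No gene of KMS11 was called as responding differently with BATF than with eGFP in the edgeR fit used here, for pomalidomide, GNE-781 or both drugs. The replicate block called 5, 0 and 6, and the fit with no low-count filter 79, 24 and 72. At an unadjusted p under 0.05 there were 628, 115 and 300 genes, and DESeq2 called 10, 2 and 8. Between these responses IRF4 differed by 1.40 ± 0.49, 0.91 ± 0.49 and 0.08 ± 0.49. As a list, S phase genes had 0 of 31 called (0 up and 0 down adjusted over the list alone) for both drugs. Their median of 0.54 gave adjusted p = 6.2e-05, and adjusted p = 0.82 with an estimated correlation. Leaving out BATF both-drug replicate 2 called 2 genes for both drugs.

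The lines were compared by testing whether the effects in KMS11 and JJN3 cells with eGFP differed. For both drugs 90 genes differed, 41 more positive in KMS11 and 49 more negative. Higher in KMS11 were the responses of CD38 (log2 difference 4.15 ± 0.53, adjusted p = 0.001), FBP1 (log2 difference 5.92 ± 1.25, adjusted p = 0.04) and SAMD9L (log2 difference 3.51 ± 0.56, adjusted p = 0.0073), genes that fell in JJN3. CD79B, part of the antigen receptor (-2.33 ± 0.41), ETS1 (-1.80 ± 0.34) and POU2AF1 (-1.57 ± 0.28) responded more negatively in KMS11, as did RIMS3, a synaptic scaffold (-4.36 ± 0.82). Interferon-stimulated genes had 2 up and 0 down of 44 (6 and 0 adjusted over the list alone) and antigen presentation 1 up and 0 down of 22 (4 and 0 adjusted over the list alone). The interferon median was 1.61 (adjusted p = 1.9e-12, and adjusted p = 0.58 with an estimated correlation). For the antigen presentation list the median was 0.39 (adjusted p = 8.7e-05, and adjusted p = 0.58 with an estimated correlation). S phase genes, with a median difference of -0.30, did not differ as a list (adjusted p = 0.14). Leaving out libraries gave 23 and 18 without JJN3 vehicle replicate 1 and 2, 13 and 13 without JJN3 both-drug replicate 1 and 2, 38 and 28 without KMS11 vehicle replicate 1 and 2 and 39 and 30 without KMS11 both-drug replicate 1 and 2, and other settings 3 without kidney-line libraries to 842 with no low-count filter.

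For pomalidomide 5 genes responded more positively in KMS11, and other settings called 0 without kidney-line libraries to 220 with no low-count filter. The 5 were SNTB1, a syntrophin (2.36 ± 0.33), SIPA1L1, a GTPase activator (1.82 ± 0.28), STEAP1, a metalloreductase family member (1.64 ± 0.27), ANKMY2, an ankyrin repeat protein (1.42 ± 0.24), and the antisense transcript RP11-713M15.2 (2.70 ± 0.46), chosen after its values were seen and assigned without a stated strand setting. The count was 4 without KMS11 pomalidomide replicate 1 and 0 without each of the other 7 libraries. For GNE-781 the fit used here called 0 genes, with 1351 at an unadjusted p under 0.05, 43 called by DESeq2 and 409 by edgeR with no low-count filter, and 2 genes were called without KMS11 GNE-781 replicate 1. The effect of BATF differed between lines in 2 genes, VPS37B, a sorting protein (-1.63 ± 0.24), and TNFAIP8, an apoptosis regulator (-1.43 ± 0.23). Leaving out libraries called 0 and 0 without JJN3 eGFP vehicle replicate 1 and 2, 0 and 0 without JJN3 BATF vehicle replicate 1 and 2, 1 and 0 without KMS11 eGFP vehicle replicate 1 and 2 and 3 and 0 without KMS11 BATF vehicle replicate 1 and 2, and other settings 0 with only the groups of the contrast to 819 with no low-count filter. 

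The calls with both drugs were shared between lines more often than independent draws would give. Among 17075 genes tested in both, 388 were up in both lines and 759 down in both, against 102.8 and 151.6 for independent draws of the same sizes, and 16 went opposite ways against 250.9. These 2 sets had separate controls, but genes are not independent of each other, so no p is given. Of the 3110 JJN3 calls tested in KMS11, 90.5% had the same sign there. For pomalidomide 12 genes were shared (0.90 expected), for GNE-781 3 (0.15) and for BATF 1, BATF itself (0.023). Between eGFP and BATF cells of JJN3, which also had separate controls, 80 genes were shared for pomalidomide (1.48 expected), 21 for GNE-781 (0.12) and 251 for both drugs (31.4). In KMS11 the shared genes numbered 11 (0.064 expected), 15 (0.060) and 1612 (163.3).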

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

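Some tests were chosen after the results they bear on were seen, and the others before. The former were those on sources of foreign transcripts, a batch per replicate number and separate handling of eGFP and BATF cultures.

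Responses differed between JJN3 cells with BATF and with eGFP in 1 gene for pomalidomide, 1 gene for GNE-781 and 397 genes for both drugs, by a test of the difference itself. The cell lines differed in 5 genes for pomalidomide, 90 for both drugs and 2 for the effect of BATF, by the same kind of test. Spike-in sequences, which no comparison uses, took counts in all 32 libraries, with a largest share of 0.0678%, on 74 of the 92 sequences. The labels do not say whether spike-in RNA was added, and no library without such counts exists in the series.

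Genes foreign to myeloma cells were present in some libraries. In the groups with 1 carrying library of 2, the listed genes of 5 blood cell types had higher medians in the carrying library, with the lowest median log2 ratio at 3.50 (monocytes) and the highest at 6.17 (red cells), and the 8 listed genes of an embryonic kidney line had a median of 4.12. RNA of blood cells and RNA of such a line are each a candidate source, since all listed genes of the blood types, and 7 of the 8 of the kidney line, were at least 2-fold higher by their median over the groups. A response of the myeloma cells to drug or BATF was excluded for the blood genes, because in 9 groups 1 library carried them and its partner, treated alike, did not. At which step the RNA entered, and whether as cells, RNA or reads, was not tested.

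Libraries with the same replicate number deviated together. The difference between replicate 1 and 2 correlated across genes between all pairs of KMS11 groups, with a lowest r of 0.33 after genes of other cells were left out, so those genes are excluded as the whole source. A batch per replicate number is consistent with this in KMS11. In JJN3 the lowest of the 28 correlations was -0.18, which speaks against 1 batch over all 8 groups, while the mitochondrial share was higher in replicate 1 in 8 of 8, so such a batch cannot be told apart there. Among the groups with BATF alone the 6 correlations were 0.38 to 0.82, so a batch within those cultures is a candidate cause there too. Among those with eGFP the lowest was 0.082, too low to count for a batch and not negative, which leaves it open. Sequencing depth cannot be told apart, as replicate 1 was deeper in 13 of 16 groups.

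By the list median, S phase genes responded less negatively to both drugs in JJN3 cells with BATF than with eGFP, with a log2 difference of 1.73 (quartiles 1.63 and 2.08), and 2.12 and 1.60 in the 2 replicates. Without the libraries that carried blood genes, 3 of the 8 compared, the median was 1.20 (quartiles 0.96 and 1.60), with all 31 genes above 0. With BATF that fit sets both-drug replicate 1 against vehicle replicate 2, so its median is confounded with replicate number. It cannot exclude blood RNA as the source. Called S phase genes went from 15 to 0 in that fit, and G2/M genes from 11 to 0 with their median going from 1.38 to 0.79. The medians were smaller there and 3 residual degrees of freedom were left in place of 8 (both libraries of GNE-781 with BATF stayed in the fit), while the median standard error of the S phase genes went from 0.45 to 0.32. Without kidney-line libraries the S phase median was 1.47, again with 0 calls. A difference already present with vehicle was excluded: BATF over eGFP stood at 1.42 with both drugs but at -0.36 with vehicle (0.014 without kidney-line libraries). Separate handling of the eGFP and BATF cultures cannot be told apart, because the 16 correlations of replicate deviations between them ran from -0.18 to 0.40 and handling would follow the same split as BATF. An action of BATF on division under both drugs was not tested, since the series holds no measure of division or cell number.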

How the results depend on the processing

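Leaving genes or libraries of other cells out was chosen after the data were seen, and the other alternatives were planned. Counts of called genes follow a fixed order within each line, namely pomalidomide, GNE-781 and both drugs with eGFP, both drugs against pomalidomide and against GNE-781, departure from additivity, BATF against eGFP, pomalidomide, GNE-781 and both drugs with BATF, and the difference that BATF made to each of these 3 responses. Between the lines the order is pomalidomide, GNE-781, both drugs and BATF. As reported the counts were 218, 43, 3180, 896, 798, 0, 217, 161, 80, 357, 1, 1 and 397 in JJN3, and 97, 117, 2931, 6, 71, 0, 3, 17, 19, 2129, 0, 0 and 0 in KMS11, and 5, 0, 90 and 2 between the lines. With RLE size factors they were 204, 41, 3164, 895, 779, 0, 220, 151, 75, 369, 1, 1 and 379 in JJN3, and 102, 125, 3019, 6, 70, 0, 3, 18, 19, 2164, 0, 0 and 0 in KMS11, and 5, 0, 105 and 1 between the lines. With DESeq2 they were 651, 483, 3962, 1649, 1423, 55, 677, 512, 386, 1021, 7, 18 and 1218 in JJN3, and 933, 2038, 4506, 416, 572, 3, 215, 306, 529, 4129, 10, 2 and 8 in KMS11, and 45, 43, 442 and 75 between the lines. With no low-count filter they were 740, 736, 3666, 1640, 1293, 165, 1884, 696, 576, 1200, 47, 257 and 1333 in JJN3, and 1447, 2061, 4209, 1046, 1008, 90, 568, 496, 1048, 4020, 79, 24 and 72 in KMS11, and 220, 409, 842 and 819 between the lines. With a replicate block they were 573, 267, 4690, 1833, 1624, 18, 586, 381, 252, 983, 1, 1 and 1355 in JJN3, and 2981, 4660, 7254, 1460, 1213, 0, 303, 467, 2027, 6957, 5, 0 and 6 in KMS11, and 6, 0, 260 and 16 between the lines. With all 32 libraries in 1 fit they were 23, 10, 1627, 148, 110, 0, 102, 41, 10, 140, 0, 0 and 15 in JJN3, and 463, 1199, 3969, 67, 255, 0, 65, 94, 87, 3569, 1, 0 and 0 in KMS11. With only the groups of the contrast, which leaves 2 residual degrees of freedom for a pair of groups, they were 2035, 613, 6072, 4422, 2916, 394, 0, 0, 0, 0, 0, 0 and 1 in JJN3, and 0, 0, 1145, 0, 0, 0, 0, 0, 0, 489, 0, 0 and 0 in KMS11, and 1, 0, 73 and 0 between the lines. Without genes of other cells they were 231, 82, 3263, 933, 828, 0, 234, 169, 93, 380, 1, 1 and 417 in JJN3, and 144, 149, 3077, 6, 87, 0, 13, 19, 21, 2301, 0, 0 and 0 in KMS11, and 7, 0, 105 and 1 between the lines. Without libraries carrying blood genes they were not run, 7, 2066, 487, 319, 0, 149, 27, not run, 190, 1, not run and 31 in JJN3, and not run, 0, 73, 0, 0, 0, not run, not run, 0, 249, not run, 0 and 0 in KMS11, and not run, 0, 15 and 1 between the lines. Without libraries carrying kidney-line genes they were 30, 6, 1848, not run, not run, 0, 37, 25, 9, 83, 0, 0 and 4 in JJN3, and 0, 0, 0, 0, 0, 0, not run, not run, not run, not run, not run, not run and not run in KMS11, and 0, 0, 3 and not run between the lines. Comparisons not run had no carrying library or a group in which both libraries carried those genes, and such groups stayed in the fits of the others. Over the fits that left out 1 library they ranged over 0 to 40, 1 to 4, 1172 to 1453, 84 to 170, 97 to 201, 0 to 0, 36 to 161, 60 to 105, 1 to 54, 87 to 363, 0 to 1, 0 to 2 and 11 to 978 in JJN3, 3 to 50, 3 to 134, 92 to 2466, 0 to 3, 0 to 20, 0 to 0, 0 to 2, 0 to 4, 0 to 6, 196 to 693, 0 to 0, 0 to 0 and 0 to 2 in KMS11 and 0 to 4, 0 to 2, 13 to 39 and 0 to 3 between the lines, where the lone library of a group is assumed to vary like the other groups. The cause of these moves was not tested, beyond the fewer libraries that some settings leave.

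Shared calls in the order pomalidomide, GNE-781, both drugs and BATF were 12, 3, 1147 and 1 between the lines and 80, 21, 251, 11, 15 and 1612 between eGFP and BATF cells, with JJN3 before KMS11. In the same order they were 111, 124, 1935 and 55, and 285, 137, 598, 179, 417 and 3172 with DESeq2. Without genes of other cells they were 13, 10, 1204 and 3, and 86, 30, 266, 13, 15 and 1740. Of the 540 list tests 211 were called with the preset correlation, 4 with an estimated one and 51 with fry. Fry asks whether the genes of a list move 1 way on balance, not against other genes. Of the 497 calls of named genes, 493 kept their call with RLE size factors, 493 with DESeq2, 497 with the replicate block, 467 with no low-count filter and 496 without genes of other cells. Of those in comparisons that were run, 258 kept it with all 32 libraries in 1 fit, which removes no library and has more residual degrees of freedom (the cause was not tested), 262 with only the groups of the contrast, 178 without libraries carrying blood genes and 85 without libraries carrying kidney-line genes. No call of a named gene reversed its direction, while 160 values of named genes without a call changed sign in at least 1 setting. Of 28 list medians followed through the settings, 5 changed sign, all without libraries carrying blood or kidney-line genes, whose values follow in that order. In JJN3 the interferon-stimulated genes went from -0.35 to 0.60 and 0.30 in the difference BATF made to the response to both drugs, and from 0.31 to -0.48 and -0.23 in BATF over eGFP with vehicle. The G2/M genes went from 0.13 to -0.38 and -0.17 with both drugs in cells with BATF, and from -0.25 to 0.039 and 0.064 in BATF over eGFP with vehicle. There the S phase genes went from -0.36 to 0.014 without kidney-line libraries. The cause was not tested. Depth and the spread between 2 libraries limit small changes, as in the simulation.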

Other observations

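The sign test on mitochondrial counts was chosen after its values were seen. With pomalidomide CD38 rose in cells with BATF, to 84.6 ± 7.2 CPM in JJN3 and 88.1 ± 18.4 CPM in KMS11. In cells with eGFP it stood at 17.8 ± 0.552 with vehicle and 12.2 ± 0.814 CPM with pomalidomide in JJN3, and at 2.85 ± 1.05 and 8.92 ± 1.78 CPM in KMS11. With GNE-781 it stood at 3.78 ± 0.0687 CPM in JJN3 cells with eGFP and at 22.6 ± 0.0565 CPM in those with BATF. In KMS11 the difference that BATF made to the pomalidomide response was not called for CD38 or any other gene in the edgeR fit used here, and DESeq2 called 10 genes.

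TNFRSF17 fell with both drugs in JJN3 cells with BATF, to 44.8 ± 0.304 from 183 ± 28.5 CPM. It fell less than with eGFP (difference 0.81 ± 0.17, adjusted p = 0.034). IRF4 had 1358 ± 411 against 1234 ± 213 CPM. BMF stood at 136 ± 54.3 CPM with both drugs and 52.5 ± 18.6 with vehicle in these cells. In KMS11 cells with eGFP, LGALS3BP stood at 31 ± 17 CPM with GNE-781. FGFR3 stood at 2699 ± 901 CPM in KMS11 and 39.4 ± 0.0349 in JJN3 with vehicle and eGFP.

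XBP1 had 0 counts in every library, although protein-disulfide and chaperone genes of its programme were counted. Its annotated interval lies wholly inside that of CTA-292E10.9, an antisense gene on the opposite strand (chromosome 22, 28784360 to 28809287), which had 21829 counts in total and 11.6 to 58.6 CPM per library. How the reads were assigned was not tested, since the table holds no reads. A second identifier of SP110 on chromosome 2 was at 0 as well, and these were the 2 of 405 distinct listed genes without counts. In all, 1000 of 19814 protein-coding genes had no count in any library.

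The spread between replicates, pooled in the fits, differed by population. Over counting noise, the chi-square per degree of freedom between the 2 libraries of a group was 7.05 to 16.4 in JJN3 cells with eGFP, 44.5 to 80.7 in JJN3 cells with BATF, 48.3 to 72.4 in KMS11 cells with eGFP and 56.9 to 86.9 in KMS11 cells with BATF. The share of counts on mitochondrial genes, 1.08 to 2.83% over the libraries, was higher in replicate 1 in 16 of 16 groups (exact two-sided sign test, p = 3.05e-05). The 10 most abundant genes took 2.78 to 3.97% of counts, so no library was dominated by a few transcripts.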
